A study of Mus musculus with 50 samples.

How the data were processed

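Total RNA of maternal livers (left lateral lobe, snap frozen) and of livers of fetuses described as female, 1 drawn at random per litter, was hybridised to mouse whole-transcript Affymetrix arrays, per the labels' protocols. The labels state that RNA integrity numbers were above 5 and 260/280 ratios above 2. The deposited values of the authors are log2 signals made with RMA, per the submitters' processing notes, which also name the mouse build mm10 and give no versions. RMA as a method corrects background, normalizes by quantiles and summarises probes by median polish. Whether all 50 arrays were processed together is not given in the sources used here. The values cover 72688 features: 65956 transcript clusters and 6732 controls, of which 5222 are negative controls.

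Signals of such arrays are relative. A level near background is compressed, a very bright probe has little range left, and quantile normalization gives each array nearly one distribution, so a shift of most genes in one direction would be partly removed. The highest mean level of any gene was 13.55 in maternal and 13.51 in fetal liver. The median per array lay between 5.15 and 5.34, the 95th percentile of the negative controls between 7.38 and 8.18, and 4393 to 7488 genes per array lay above that percentile. The number of arrays limits the precision of each comparison.

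Gene names came from the platform annotation given with the series. Of its 32750 probes, 30604 had 1 symbol, 612 had several symbols of 1 gene and 1534 had symbols of several genes and were left out. Symbols were updated through the gene identifier for 827 of the 22818 probes matched that way. The other 33206 transcript clusters are unnamed here. For the 364 genes with more than 1 probe the brightest was used, which gave 30743 genes. Some genes of the fixed lists are not reported here.

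Arrays were grouped by sample title, which matched the recorded characteristics. The source names of 2 fetal arrays give another group: fetal PFOA5 replicate 6 would be GenX2, and fetal GenX2 replicate 5 would be GenX10. The fits were repeated without these arrays and with the source names followed.

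Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 fit of 5 groups per tissue and 1 fit of 10 groups for comparisons between tissues. Data were handled with data.table (version 1.17.8), and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15; figures were drawn with matplotlib 3.10.9. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and all tests were two-sided. The 21 comparisons were each exposure against control in each tissue, dose against dose, compound against compound, fetal against maternal controls, and the difference of each exposure's effect between tissues. Intervals are 95% confidence intervals of the log2 difference.

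Gene lists numbering 41, which cover pathways of lipid, bile acid and xenobiotic metabolism, stress responses, and markers of liver, blood and neighbouring cells, were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives other than those named last below. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and on its own with fry. Adjusted p values of lists run over the lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone.

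The named genes follow a fixed rule. It takes up to 5 rises and 5 falls per comparison, the largest past the threshold with every array of the first group on the same side of the second group's mean (for effects between tissues, ranked by size alone). It adds up to 3 members of each list with the smallest adjusted p, or the member with the smallest p where none passed, and 28 anchor genes, of which 22 were measured. Symbols of predicted genes, small RNAs and receptor or immunoglobulin families were left out of the largest changes. Genes outside it are said to have been chosen after their values were seen.

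Overlaps of comparisons sharing controls were set beside independent lists, 20 simulated draws of unchanged groups against the same controls, and 20 control splits. Other splits of the arrays were drawn 100 times per comparison. The procedure was tested on data simulated for 30743 genes. For maternal PFOA5 against control it called 88.1% of genes changed by 0.5 (log2) and 100% of those changed by 1. For fetal PFOA1 these shares were 79.1% and 97.0%, and for fetal GenX10 89.6% and 100%. False calls were 6.8%, 7.1% and 5.4% of the calls. These rates need not hold for real arrays, where other splits called up to 3297 genes (fetal GenX10).

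Alternatives covered variance moderation with an intensity trend, a filter on dim genes, a repeated quantile normalization, median centring, averaged probes, array weights, a 1.5-fold minimum, the samples in the fit, a replicate block, an erythroid score as a covariate and leaving out each array in turn. A fit without the 2 fetal arrays with Y-linked signal and one with the negative control median as a covariate were added after the data were seen.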

Results

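Liver transcript levels were measured on 50 Affymetrix whole-transcript arrays from CD-1 mice, an outbred strain, at gestational day 17.5. Pregnant mice had been dosed daily by gavage with vehicle, with perfluorooctanoic acid (PFOA) at 1 or 5 mg/kg/day, or with GenX at 2 or 10 mg/kg/day. PFOA is a straight-chain perfluorinated carboxylic acid, and GenX (hexafluoropropylene oxide dimer acid) is a shorter, branched perfluorinated ether carboxylic acid. Each of the 5 maternal groups had 5 arrays, and the fetal groups had 5 arrays except PFOA at 5 mg/kg/day (6 arrays) and GenX at 10 mg/kg/day (4 arrays). As far as the labels say, the replicates were separate dams and fetuses of separate litters. The labels call maternal and fetal livers matched without naming the pairs, so comparisons between tissues treat the arrays as independent. The groups are called maternal or fetal PFOA1, PFOA5, GenX2 and GenX10 by dose. The doses of the compounds were not matched, so levels under PFOA and GenX are set side by side.

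The labels describe the fetuses as female, but fetal control replicate 3 and fetal GenX2 replicate 2 had Xist, the transcript of the inactive X chromosome, at 5.39 and 4.50. Xist was at 10.52 to 11.48 on the other 23 fetal arrays. In the same 2 arrays the Y-linked Eif2s3y was at 6.49 and 6.10, against 3.63 to 3.80 on the others. For fetal PFOA5 replicate 6 and fetal GenX2 replicate 5 the labels disagree among themselves about the group, and the sample titles were followed.

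Every exposure raised genes of fatty acid oxidation in both tissues, and the number of changed genes differed widely. Of 30743 genes, 10 changed in maternal PFOA1, 6109 in maternal PFOA5, 1036 in maternal GenX2 and 4232 in maternal GenX10. In fetal liver 293 changed with PFOA1, 1042 with PFOA5, 2070 with GenX2 and 2851 with GenX10. Changes are given as log2 differences ± standard error, with levels as mean log2 signal ± SD. Where every array of a group lay at or below the 95th percentile of its negative controls, a gene is called not well above background (dim) in that group. Its log2 change is then a difference of signals with no exact fold, and a fold is given as at least N-fold, with the dim arrays set at that percentile. Of 940 named gene calls between groups, the lower group was dim in 238 and both groups in 154. A gene list's p is followed by the one with an estimated correlation where that ended the call, and the other list calls given held with it.

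**Figure D1:**
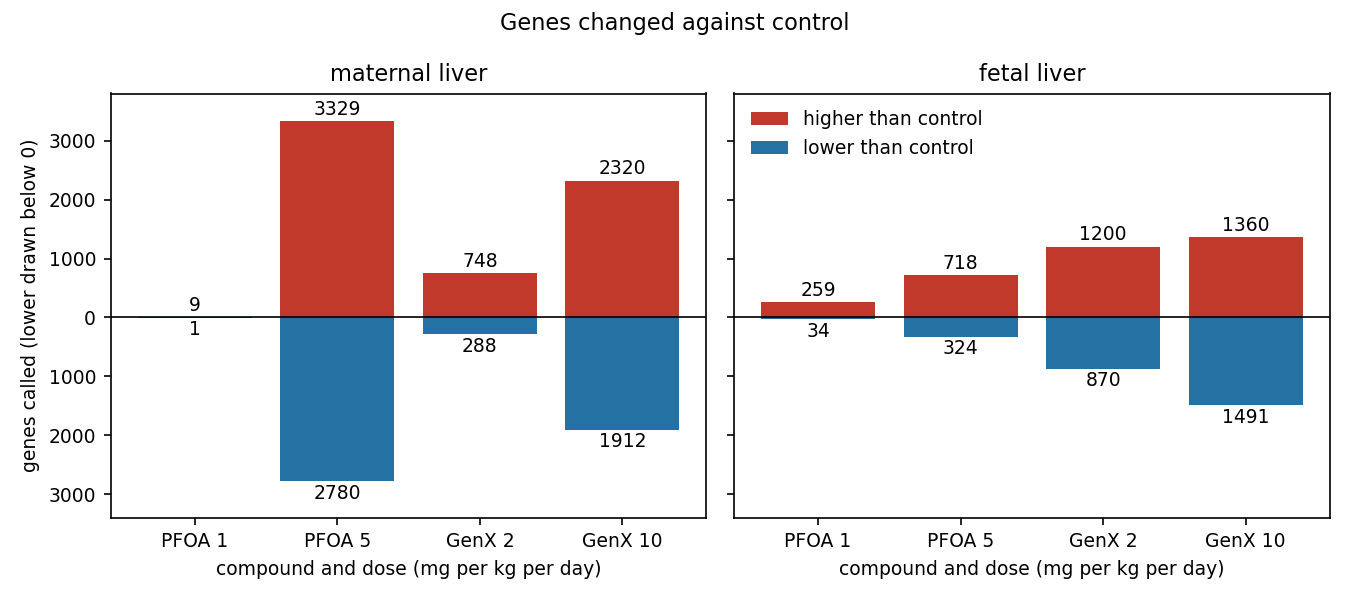
Number of genes past an adjusted p of 0.05 in the comparison of each exposure with control, as bars of higher genes above 0 and lower genes below it, by tissue, compound and dose. Maternal PFOA5 has the most genes of the 8 exposures (3329 higher, 2780 lower) and maternal PFOA1 the fewest (9 higher, 1 lower).

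At the lower PFOA dose, maternal liver had 10 changed genes, 9 higher and 1 lower. Ehhadh, a peroxisomal β-oxidation enzyme, rose by 1.39 ± 0.20 (2.62-fold, adjusted p = 0.0075). Scd1, which desaturates fatty acids, rose by 1.13 ± 0.15 (adjusted p = 0.0019). Pdk4, a kinase that restrains glucose oxidation, rose by 1.93 ± 0.34, and the other named calls were Pltp, Fabp5, Scd3 and Cyp4a32 (higher) and Tbc1d9 (lower), beside 2 higher gene models, with Fabp5, Scd3 and Tbc1d9 dim in both groups. Of genes of peroxisomal fatty acid oxidation, 1 of 27 (15 adjusted over the list alone, median log2 change 0.39, camera adjusted p = 7.8e-27) rose. Genes for microsomal omega oxidation of fatty acids had 7 of 11 members higher and 1 lower when adjusted over the list alone (1 higher over all genes, median log2 change 0.84, camera adjusted p = 8.4e-11). Of mitochondrial oxidation genes, 13 of 21 passed only when adjusted over the list alone (median log2 change 0.29, camera adjusted p = 1.3e-20, adjusted p = 0.059 with an estimated correlation).

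These calls rested on few arrays, and maternal PFOA1 replicate 1 lay at control level. Its Ehhadh was 10.54, against 11.94 to 12.36 on the other 4 arrays of the group and 10.36 to 10.59 in controls. Without it 127 genes changed, among them Ehhadh (log2 change 1.72), Cyp4a14 (3.69), Vnn1 (1.84) and Acaa1b (1.40), whose values over all 5 arrays (2.90, 1.41 and 1.08 for the last 3) missed the threshold. The count was 2 without control replicate 1 or 4 or PFOA1 replicate 2 or 5. It was 3 without control replicate 3 or 5 and 1 without PFOA1 replicate 3 or 4. Ehhadh missed the threshold without replicate 3 (adjusted p = 0.050) or replicate 4 (0.051), and Scd1 kept its call in each of these fits. Pdk4, Pltp, Fabp5, Scd3, Cyp4a32 and Tbc1d9 were each lost in at least 8 of the 10 fits that left out an array. With only controls and PFOA1 fitted limma called 0 genes, with 1719 at an unadjusted p under 0.05 (main fit 1532), near the chance level.

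The higher PFOA dose changed 6109 genes in maternal liver, 3329 higher and 2780 lower. Among the large rises were Cyp4a12a and Cyp4a12b, fatty acid ω-hydroxylases of male-biased expression. Cyp4a12a went from 5.04 ± 0.06 in controls, where it was dim, to 12.18 ± 0.09 (SD, n = 5 each), at least 23.6-fold (log2 change 7.13 ± 0.77, adjusted p = 3.2e-07). Pdk4 rose by 4.75 ± 0.34, Cyp4a14, another ω-hydroxylase, by 4.21 ± 0.63, and Ly6d by 3.94 ± 0.29. Large falls were in the sulfotransferases Sult2a1 (−4.21 ± 1.12), Sult3a1 (−3.60 ± 0.94) and Sult2a2 (−3.51 ± 0.93). Pigr, the receptor that carries IgA into bile, fell by 3.61 ± 0.34, and the ω-hydroxylase gene Cyp4f14 had a change of −3.46 ± 0.29. That all 5 exposed arrays lay on the stated side of the control mean was a condition for choosing these genes, not a separate result. Ly6d was dim in controls, Pigr and Cyp4f14 were in PFOA5, and the 3 sulfotransferases were above background on 1, 2 and 1 of 5 PFOA5 arrays.

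Fatty acid oxidation rose together in maternal PFOA5. In peroxisomal oxidation 25 of 27 (25 adjusted over the list alone, median log2 change 1.06, camera adjusted p = 1.9e-34) rose, among them the thioesterases Acot4 (2.50) and Acot3 (2.69), Pex11a, which drives peroxisome division (2.86), and Ehhadh (2.53), of which the first 3 were dim in controls. In mitochondrial oxidation 21 of 21 (21 adjusted over the list alone, median log2 change 1.24, camera adjusted p = 7.2e-34) rose, with Acot2 (3.60), Cpt2, which reforms acyl-CoA inside mitochondria (1.42), and Hadha of the trifunctional protein (1.24). Of PPAR-responsive lipid handling genes, 20 of 28 (22 adjusted over the list alone, median log2 change 0.90, camera adjusted p = 2.1e-23) rose, including the lipid droplet coat gene Plin2 (1.48) and Cd36, a fatty acid carrier (1.81). Microsomal omega oxidation had 8 of 11 genes higher and 1 lower (8 and 2 adjusted over the list alone, median log2 change 2.00, camera adjusted p = 1.8e-07, adjusted p = 0.057 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 28 (23 adjusted over the list alone, median log2 change 0.36, camera adjusted p = 8.7e-13, adjusted p = 0.10 with an estimated correlation). Cholesterol synthesis and uptake genes rose in 11 of 19 (13 adjusted over the list alone, median log2 change 0.43, camera adjusted p = 3.1e-10, adjusted p = 0.065 with an estimated correlation), with Hsd17b7 at 1.45 and Fdps at 0.82. Fatty acid and triglyceride synthesis had 11 of 20 genes higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 1.8e-09, adjusted p = 0.073 with an estimated correlation).

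Targets of the receptors CAR and PXR rose in maternal PFOA5 in 10 of 22 (12 adjusted over the list alone, median log2 change 0.41, camera adjusted p = 4.7e-08, adjusted p = 0.10 with an estimated correlation). Cyp2b10, a classic CAR target, rose by 2.33 ± 0.40, adjusted p = 0.00017, and Cyp2c55 by 2.46 ± 0.41, adjusted p = 0.00014. Of organic anion transporters 5 of 13 were higher and 2 lower (the same adjusted over the list alone, median −0.02 but mean 0.43, camera adjusted p = 0.012, adjusted p = 0.16 with an estimated correlation). The efflux pumps Abcc3 and Abcc4 rose by 3.51 ± 0.30 and 3.42 ± 0.20, and Alas1, which starts haem synthesis, by 1.68 ± 0.16. The list of NRF2 targets had 11 of 15 genes higher and 1 lower (11 and 3 adjusted over the list alone, camera adjusted p = 5.6e-07, adjusted p = 0.075 with an estimated correlation), with Nqo1 at 0.77. Cyp2c55, Abcc3, Abcc4 and Nqo1 were dim in controls.

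Complement and coagulation genes fell in maternal PFOA5 in 26 of 34 (27 and 1 the other way adjusted over the list alone, median log2 change −0.46, camera adjusted p = 9.7e-14, adjusted p = 0.077 with an estimated correlation), among them the lectin Mbl2 (−1.44) and complement C4b (−1.09). The acute phase list had 15 of 20 genes lower and 1 higher (camera adjusted p = 4.5e-06, adjusted p = 0.095 with an estimated correlation). Growth hormone and sex-biased genes had 11 of 18 lower and 1 higher (12 and 1 adjusted over the list alone, camera adjusted p = 0.00020), including Mup21, a major urinary protein (−2.77). Pericentral hepatocyte markers fell in 7 of 12 (9 adjusted over the list alone, median log2 change −0.42, camera adjusted p = 8.7e-07), with Gulo, which completes vitamin C synthesis, at −1.71. Cell cycle genes fell in 15 of 23 (18 adjusted over the list alone, median log2 change −0.34, camera adjusted p = 1.0e-06, adjusted p = 0.23 with an estimated correlation), including Top2a (−0.88). Mature hepatocyte markers had 2 of 14 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.69). Mup21 was dim in PFOA5, and Top2a in both groups. Macrophage and Kupffer cell markers rose in 6 of 16 (9 adjusted over the list alone, median log2 change 0.36, camera adjusted p = 3.5e-05, adjusted p = 0.29 with an estimated correlation). Cyp7a1, which starts bile acid synthesis, missed the threshold (−1.41, 95% interval −2.48 to −0.33). With each array centred on its median the calls were 3997 higher and 1287 lower, and limma's array weights gave 4327 higher and 5310 lower.

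GenX at 2 mg/kg/day changed 1036 genes in maternal liver, 748 higher and 288 lower. Cyp4a12a rose at least 5.4-fold (log2 change 5.00 ± 0.77, adjusted p = 0.00023), from 5.04 ± 0.06 to 10.04 ± 1.53, and Cyp4a12b by 4.84 ± 0.74. Replicate 1 had Cyp4a12a at 12.39 and the other 4 arrays at 8.21 to 10.28, and without it the rise was at least 3.6-fold. Cyp4a14 rose by 3.95 ± 0.63, Pdk4 by 3.89 ± 0.34 and the cytosolic thioesterase Acot1 by 2.96 ± 0.31. Large falls were in Serpina16 (−1.89 ± 0.38), Lrtm1 (−1.80 ± 0.28), the proliferation marker Mki67 (−1.68 ± 0.37), the glutamate transporter Slc1a2 (−1.57 ± 0.32) and Orm2, an acute phase glycoprotein (−1.55 ± 0.33). Cyp4a12a and Cyp4a12b were dim in controls, and Serpina16, Lrtm1 and Mki67 in GenX2.

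By group, peroxisomal oxidation genes rose in maternal GenX2 in 22 of 27 (25 adjusted over the list alone, median log2 change 0.74, camera adjusted p = 1.5e-51) and mitochondrial ones in 21 of 21 (21 adjusted over the list alone, median log2 change 0.82, camera adjusted p = 2.1e-51). Examples were Ehhadh (2.24), Acot2 (2.63) and Acadm, a medium-chain acyl-CoA dehydrogenase (0.95). PPAR-responsive lipid handling genes rose in 13 of 28 (18 adjusted over the list alone, median log2 change 0.49, camera adjusted p = 2.9e-25). Genes of cholesterol synthesis and uptake rose in 11 of 19 (19 adjusted over the list alone, median log2 change 0.53, camera adjusted p = 3.2e-23), with Hsd17b7 (1.06), Hmgcs1 (0.85) and Pmvk (0.78), enzymes of the sterol pathway. Oxidative phosphorylation rose in 7 of 28 (21 adjusted over the list alone, median log2 change 0.27, camera adjusted p = 3.9e-19) and fatty acid and triglyceride synthesis in 10 of 20 (16 adjusted over the list alone, median log2 change 0.58, camera adjusted p = 1.6e-16). Cell cycle genes fell in 13 of 23 (17 adjusted over the list alone, median log2 change −0.37, camera adjusted p = 4.2e-14, adjusted p = 0.058 with an estimated correlation), with the mitotic regulators Plk1 (−0.95) and Cdc20 (−0.71), both dim in GenX2. Acute phase genes fell in 8 of 20 (12 adjusted over the list alone, median log2 change −0.43, camera adjusted p = 1.1e-09). Cyp2b10 missed the threshold (0.40, 95% interval −0.43 to 1.23) and changed by 0.05 without replicate 1, and Cyp2c55 was dim in controls and on 4 of 5 GenX2 arrays. Without maternal GenX2 replicate 4 the count rose to 2433, with array weights it was 2621, and with only controls and GenX2 fitted it was 597. Centring on array medians gave 966 higher and 164 lower.

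GenX at 10 mg/kg/day changed 4232 genes in maternal liver, 2320 higher and 1912 lower. Cyp4a12a rose at least 18.2-fold (log2 change 6.76 ± 0.77, adjusted p = 1.1e-06), from 5.04 ± 0.06 to 11.80 ± 0.29, Cyp4a12b by 6.61 ± 0.74, Pdk4 by 4.79 ± 0.34 and Cyp4a14 by 4.12 ± 0.63. Fabp3, a fatty acid binding protein typical of heart and muscle, rose by 3.61 ± 0.31, and the near copy Fabp3-ps1, whose signal may not be separate from that of Fabp3, by 4.00 ± 0.35. Large falls were in the major urinary proteins Mup21 (−3.15 ± 0.36) and Mup3 (−2.84 ± 0.26), members of a family of near-identical genes, Slc1a2 (−2.66 ± 0.32), Hamp, the hormone that limits iron uptake (−2.60 ± 0.67), and Pigr (−2.51 ± 0.34). Cyp4a12a, Cyp4a12b, Fabp3 and Fabp3-ps1 were dim in controls, and Mup21 and Slc1a2 in GenX10.

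In maternal GenX10, mitochondrial oxidation genes rose in 21 of 21 (21 adjusted over the list alone, median log2 change 1.12, camera adjusted p = 2.8e-42), peroxisomal ones in 24 of 27 (25 adjusted over the list alone, median log2 change 1.05, camera adjusted p = 2.5e-40) and PPAR-responsive lipid handling genes in 24 of 28 (24 adjusted over the list alone, median log2 change 1.24, camera adjusted p = 2.5e-33). Ehhadh rose by 2.47 and Acot2 by 3.37. In cholesterol synthesis and uptake, genes rose in 18 of 19 (19 adjusted over the list alone, median log2 change 0.90, camera adjusted p = 3.3e-30), with Hsd17b7 (1.60), Fdps (1.11) and the squalene oxidase gene Sqle (0.88). Fatty acid and triglyceride synthesis rose in 14 of 20 (15 and 1 the other way adjusted over the list alone, median log2 change 0.94, camera adjusted p = 2.9e-17), with Fasn, the fatty acid synthase, at 1.28. Oxidative phosphorylation rose in 21 of 28 (24 adjusted over the list alone, median log2 change 0.38, camera adjusted p = 5.8e-19, adjusted p = 0.062 with an estimated correlation). Complement and coagulation fell in 15 of 34 (20 and 1 the other way adjusted over the list alone, median log2 change −0.29, camera adjusted p = 4.1e-08, adjusted p = 0.20 with an estimated correlation), and acute phase genes in 13 of 20 (14 adjusted over the list alone, median log2 change −0.40, camera adjusted p = 2.7e-07, adjusted p = 0.062 with an estimated correlation). Cell cycle genes fell in 15 of 23 (19 adjusted over the list alone, median log2 change −0.38, camera adjusted p = 2.5e-08, adjusted p = 0.19 with an estimated correlation), with Rrm2 (−0.67) and Aurka (−0.66), dim in both groups. Macrophage and Kupffer cell markers rose in 4 of 16 (9 adjusted over the list alone, median log2 change 0.40, camera adjusted p = 1.8e-05, adjusted p = 0.26 with an estimated correlation). Of 22 CAR and PXR targets 3 were higher and 3 lower, and Cyp2b10 (0.23, 95% interval −0.60 to 1.05) missed the threshold, while Cyp2c55 was dim in both groups. Without maternal GenX10 replicate 1 the count was 2364, and centring on array medians gave 3046 higher and 735 lower.

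**Figure D2:**
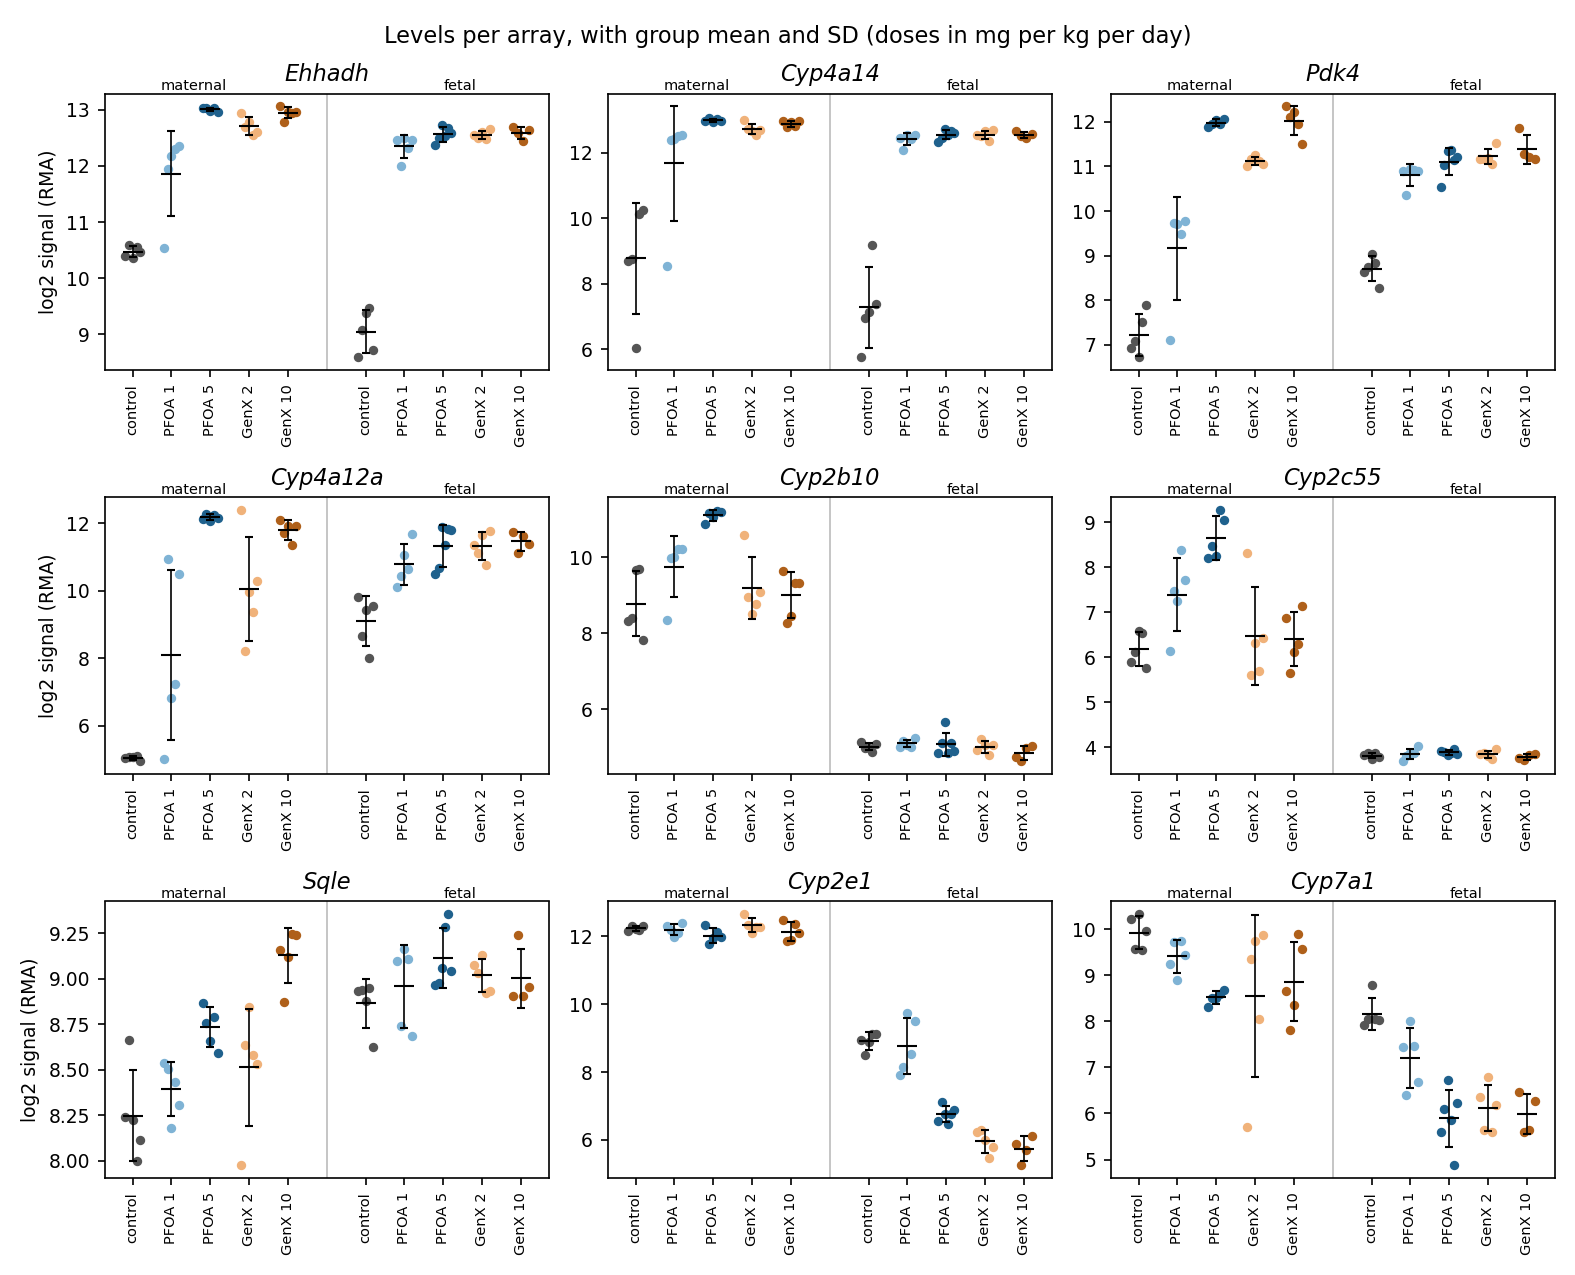
Log2 signal of 9 genes on each array, with a point for each array and a line and error bar for the group mean ± SD, by tissue and group. Maternal PFOA1 spans 10.54 to 12.36 for Ehhadh, and Cyp2e1 lies lower in fetal PFOA5, GenX2 and GenX10 (means 6.76, 5.96 and 5.74) than in fetal controls (8.92).

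In fetal liver, PFOA at 1 mg/kg/day changed 293 genes, 259 higher and 34 lower. Cyp4a14 rose from 7.28 ± 1.23 to 12.42 ± 0.19 (SD, n = 5 each), a log2 change of 5.14 ± 0.33 (adjusted p = 2.7e-10). As for Vnn1 and Cyp4a31, 1 of 5 fetal control arrays was above background, so no fold is given for fetal Cyp4a14. Its relative Cyp4a32 rose by 3.66 ± 0.31, Ehhadh by 3.30 ± 0.13 and Vnn1, a pantetheinase, by 3.02 ± 0.23. The carboxypeptidase gene Cpm (−1.17 ± 0.21), the carboxylesterase gene Ces1c (−0.98 ± 0.15) and Hsd11b1, which regenerates active glucocorticoid (−0.89 ± 0.12), fell. Mitochondrial oxidation genes rose in 16 of 21 (20 adjusted over the list alone, median log2 change 0.85, camera adjusted p = 8.8e-75), with Acot2 (2.84), the carnitine carrier Slc25a20 (1.53) and Cpt2 (1.34). Peroxisomal oxidation genes rose in 17 of 27 (24 adjusted over the list alone, median log2 change 0.80, camera adjusted p = 3.7e-65), with Acot3 (2.55) and the thiolase gene Acaa1b (2.30). PPAR-responsive lipid handling genes rose in 10 of 28 (14 adjusted over the list alone, median log2 change 0.33, camera adjusted p = 1.8e-28), with Fabp1, the liver fatty acid binding protein, at 1.61 and Angptl4, an inhibitor of lipoprotein lipase, at 1.15. Omega oxidation genes rose in 7 of 11 (7 adjusted over the list alone, median log2 change 1.11, camera adjusted p = 2.4e-26) and oxidative phosphorylation in 4 of 28 (20 adjusted over the list alone, median log2 change 0.22, camera adjusted p = 3.0e-21). Cyp7a1 (−0.96, 95% interval −1.60 to −0.32) missed the threshold. Cyp4a32, Acot3 and Angptl4 were dim in controls, Cpm in PFOA1, and Ces1c and Hsd11b1 in both groups.

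PFOA at 5 mg/kg/day changed 1042 genes in fetal liver, 718 higher and 324 lower. Large rises were in Cyp4a14 (5.28 ± 0.32, adjusted p = 3.2e-11), Cyp4a31 (3.74 ± 0.28), Cyp4a32 (3.69 ± 0.29), Acot2 (3.63 ± 0.15) and Ehhadh (3.52 ± 0.12). Large falls were in the aldehyde oxidase gene Aox3 (−2.62 ± 0.26), Cyp7a1 (−2.27 ± 0.30), the alcohol-metabolising Cyp2e1 (−2.16 ± 0.25), the paraoxonase Pon1 (−2.01 ± 0.24) and Mbl2 (−1.69 ± 0.14), all 5 dim in PFOA5. Of 14 mature hepatocyte markers 2 were higher and 2 lower (2 and 6 adjusted over the list alone, median −0.08 and mean 0.04, camera adjusted p = 0.11). Cyp2e1 went from 8.92 ± 0.26 in controls to 6.76 ± 0.23 (n = 5 and 6), at least 2.21-fold lower. Bile acid synthesis and transport had 6 of 20 genes lower and 1 higher (7 and 3 adjusted over the list alone, camera adjusted p = 0.25), including Cyp8b1 (−1.30) and Akr1d1 (−1.47) beside Cyp7a1.

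Mitochondrial oxidation genes rose in fetal PFOA5 in 18 of 21 (20 adjusted over the list alone, median log2 change 1.07, camera adjusted p = 3.1e-67), peroxisomal ones in 19 of 27 (23 adjusted over the list alone, median log2 change 0.84, camera adjusted p = 1.5e-58) and omega oxidation in 7 of 11 (8 adjusted over the list alone, median log2 change 1.40, camera adjusted p = 2.6e-24). PPAR-responsive lipid handling rose in 13 of 28 (17 adjusted over the list alone, median log2 change 0.56, camera adjusted p = 5.3e-30). Fatty acid and triglyceride synthesis rose in 9 of 20 (14 adjusted over the list alone, median log2 change 0.45, camera adjusted p = 3.1e-19), with Me1 at 2.35 and Scd1 at 1.23, and oxidative phosphorylation in 7 of 28 (18 adjusted over the list alone, median log2 change 0.19, camera adjusted p = 3.3e-16). Cholesterol synthesis and uptake genes rose in 6 of 19 (13 adjusted over the list alone, median log2 change 0.28, camera adjusted p = 5.6e-12, adjusted p = 0.065 with an estimated correlation), with Lss at 0.67. CAR and PXR targets rose in 6 of 22 (9 adjusted over the list alone, median log2 change 0.08, camera adjusted p = 3.0e-05, adjusted p = 0.065 with an estimated correlation), with Aldh1a7 at 2.73, but Cyp2b10 and Cyp2c55 were dim in every fetal group (means of 5.07 and 3.89 in PFOA5), which leaves their response unmeasured. Complement and coagulation had 6 of 34 genes lower and 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.30 with an estimated correlation), with C1ra at −0.70. Cyp4a32, Me1 and Aldh1a7 were dim in controls, and Akr1d1 and C1ra in PFOA5.

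GenX at 2 mg/kg/day changed 2070 genes in fetal liver, 1200 higher and 870 lower. Cyp4a14 rose by 5.27 ± 0.33 (adjusted p = 8.3e-11), Vnn1 by 3.73 ± 0.23, Acot2 by 3.72 ± 0.16, Cyp4a31 by 3.68 ± 0.29 and Cyp4a32 by 3.53 ± 0.31. The starch-digesting amylases Amy2b (−3.55 ± 0.53, adjusted p = 9.1e-05) and Amy2a1 (−2.88 ± 0.40, adjusted p = 3.8e-05) fell, and because amylase genes are close copies their probes may not be fully separate. Cyp2e1 (−2.96 ± 0.26), Pon1 (−2.84 ± 0.25) and Aox3 (−2.58 ± 0.28) fell too. The bile acid enzymes Cyp7a1 (−2.05), Cyp8b1 (−1.32) and Akr1d1 (−1.63) also fell. Cyp4a32 was dim in controls, Amy2a1 in both groups, and Amy2b, Cyp2e1, Pon1, Aox3, Cyp7a1 and Akr1d1 in GenX2.

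Mitochondrial oxidation genes rose in fetal GenX2 in 18 of 21 (20 adjusted over the list alone, median log2 change 1.01, camera adjusted p = 1.2e-51), peroxisomal ones in 20 of 27 (23 adjusted over the list alone, median log2 change 0.78, camera adjusted p = 1.5e-42), PPAR-responsive lipid handling in 13 of 28 (16 and 1 the other way adjusted over the list alone, median log2 change 0.26, camera adjusted p = 5.5e-19), omega oxidation in 7 of 11 (7 adjusted over the list alone, median log2 change 1.50, camera adjusted p = 1.0e-15) and oxidative phosphorylation in 11 of 28 (20 adjusted over the list alone, median log2 change 0.26, camera adjusted p = 6.4e-16). Ehhadh rose by 3.51 and Slc25a20 by 1.94. The list of cholesterol synthesis and uptake rose in 8 of 19 (9 adjusted over the list alone, median log2 change 0.34, camera adjusted p = 1.4e-09, adjusted p = 0.13 with an estimated correlation), with Lss at 0.75. The urea cycle and amino acid list had 8 of 23 genes lower and 1 higher (10 and 2 adjusted over the list alone, camera adjusted p = 0.00052, adjusted p = 0.53 with an estimated correlation), with the histidase gene Hal, dim in GenX2, at −1.11 and Gnmt at −1.06. Acute phase genes fell in 5 of 20 (8 adjusted over the list alone, median log2 change −0.16, camera adjusted p = 0.00052, adjusted p = 0.36 with an estimated correlation), with haptoglobin (Hp) at −1.44. Without fetal GenX2 replicate 4 the count was 1310, with only controls and GenX2 fitted it was 1159, and with the arrays of conflicting labels grouped by their source names it was 1260. Centring on array medians gave 1704 higher and 615 lower.

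GenX at 10 mg/kg/day changed 2851 genes in fetal liver, 1360 higher and 1491 lower. Cyp4a14 rose by 5.27 ± 0.35 (adjusted p = 2.3e-10), Vnn1 by 3.80 ± 0.25, Acot2 by 3.78 ± 0.17, Ehhadh by 3.55 ± 0.13 and Cyp4a31 by 3.51 ± 0.31. Cyp2e1 fell by 3.18 ± 0.28 (at least 2.07-fold lower, adjusted p = 2.0e-08), and Aox3 (−3.02 ± 0.29), Pon1 (−2.94 ± 0.27), Amy2b (−2.85 ± 0.56) and Amy2a1 (−2.50 ± 0.42) fell with it. Cyp7a1 (−2.17), Akr1d1 (−1.94) and Slc27a5, which activates bile acids (−1.03), were lower. Of these, Amy2a1 and Slc27a5 were dim in both groups and the other 6 in GenX10. Mitochondrial oxidation genes rose in 18 of 21 (20 adjusted over the list alone, median log2 change 1.13, camera adjusted p = 7.4e-49), peroxisomal ones in 19 of 27 (22 adjusted over the list alone, median log2 change 0.90, camera adjusted p = 1.5e-38), omega oxidation in 7 of 11 (7 adjusted over the list alone, median log2 change 1.50, camera adjusted p = 1.8e-14) and oxidative phosphorylation in 15 of 28 (22 adjusted over the list alone, median log2 change 0.30, camera adjusted p = 3.7e-18). PPAR-responsive lipid handling rose in 12 of 28 (14 and 3 the other way adjusted over the list alone, median log2 change 0.43, camera adjusted p = 3.7e-18), with Angptl4, dim in controls, at 1.86 and Plin2 at 1.58. Acute phase genes fell in 7 of 20 (11 adjusted over the list alone, median log2 change −0.28, camera adjusted p = 0.0014, adjusted p = 0.43 with an estimated correlation), with Hp at −1.37, and the complement genes C1s1 (−1.41) and C1ra (−1.08, dim in GenX10) were lower. Fasn (0.19, 95% interval −0.14 to 0.51), the fetal liver marker Afp (−0.08, 95% interval −0.18 to 0.03) and Ppara, the receptor itself (0.04, 95% interval −0.23 to 0.32), missed the threshold. The count was 1547 without fetal GenX10 replicate 1, 1844 without replicate 2 and 1751 with only controls and GenX10 fitted, and centring on array medians gave 2130 higher and 833 lower.

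Markers of red cell precursors, which fetal liver contains, had small median changes, called by camera in fetal PFOA1, PFOA5 and GenX2 and in no exposure with an estimated correlation. The erythroid list had medians of −0.09 in fetal PFOA1, −0.12 in PFOA5, 0.10 in GenX2 and 0.07 in GenX10 (camera adjusted p = 0.0019, 0.046, 0.013 and 0.14, or 0.50, 0.62, 0.72 and 0.79 with an estimated correlation). Cell cycle genes had medians of −0.13, −0.14, 0.16 and 0.14 in the same order (camera adjusted p = 5.3e-05, 0.0083, 0.0016 and 0.022, or 0.50, 0.60, 0.72 and 0.73 with an estimated correlation). Of both lists, 1 erythroid gene was called, in GenX2, and the count was the same adjusted over the list alone.

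**Figure D3:**
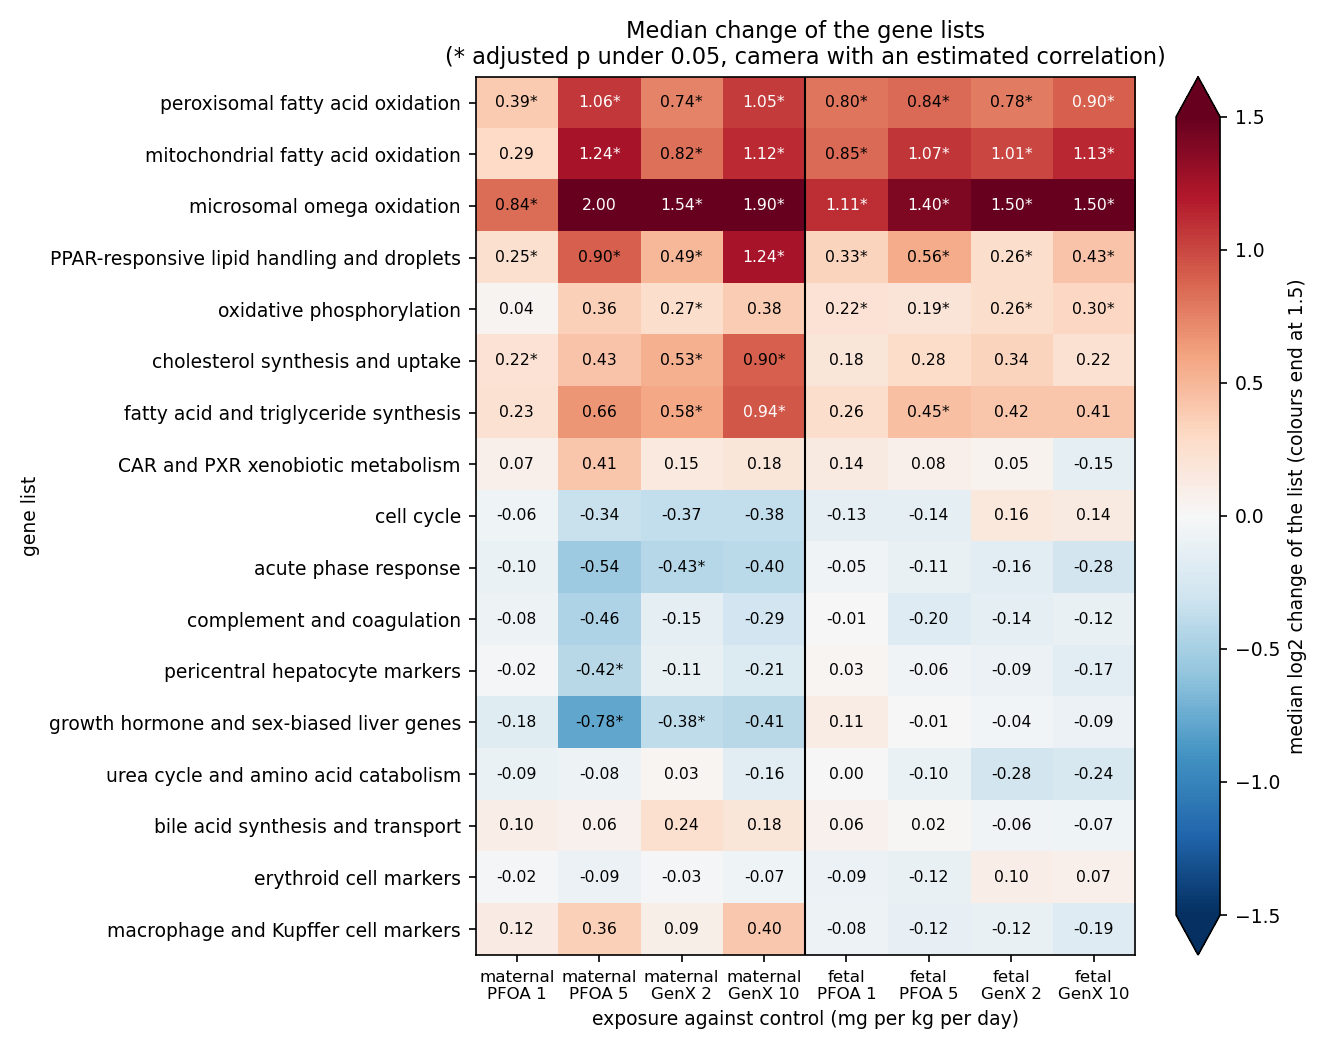
Median log2 change of 17 gene lists, down the side, in the comparison of each exposure with control, along the bottom, coloured by size and sign, with stars for lists past an adjusted p of 0.05 by camera with an estimated correlation. Mitochondrial fatty acid oxidation has medians of 0.29 to 1.24 in maternal liver and 0.85 to 1.13 in fetal liver.

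Between the PFOA doses 5748 genes differed in maternal liver, 54.4% of them higher at the higher dose. PFOA1 holds replicate 1, at control level, which can widen such gaps. Cyp4a12b (4.16 ± 0.74), Cyp4a12a (4.08 ± 0.77), Fabp3 (3.27 ± 0.31), Abcc4 (2.86 ± 0.20) and Pdk4 (2.82 ± 0.34) were higher in PFOA5. Cyp4f14 (−2.79 ± 0.29), Pigr (−2.50 ± 0.34) and Mup21 (−2.34 ± 0.36) were lower, all 3 dim in PFOA5. Mitochondrial oxidation genes were higher in 19 of 21 (21 adjusted over the list alone, median log2 change 0.86, camera adjusted p = 7.6e-26), peroxisomal ones in 23 of 27 (23 adjusted over the list alone, median log2 change 0.73, camera adjusted p = 3.6e-25) and PPAR-responsive lipid handling in 18 of 28 (21 adjusted over the list alone, median log2 change 0.70, camera adjusted p = 1.4e-16), while pericentral markers were lower in 7 of 12 (9 adjusted over the list alone, median log2 change −0.36, camera adjusted p = 1.9e-06). The count was 3637 without PFOA5 replicate 4. Centring gave 3779 higher and 1008 lower, and array weights 3798 and 4269. The GenX doses differed in 73 genes in maternal liver, with Smcp (2.12 ± 0.15), Ly6d (1.90 ± 0.29) and Cd24a (1.84 ± 0.22) higher and Mup3 (−2.08 ± 0.26) lower at the higher dose, Smcp being dim in both groups and Cd24a in GenX2. Cholesterol synthesis and uptake genes were higher in 4 of 19 (15 adjusted over the list alone, median log2 change 0.42, camera adjusted p = 4.2e-23). This count was 126, 45 and 41 without maternal GenX2 replicates 1, 2 and 5 and 35 without GenX10 replicate 1. It was 146 with all 50 arrays and 14 with only these groups.

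In fetal liver the PFOA doses differed in 15 genes, with Cyp2e1 (−2.01 ± 0.25, adjusted p = 0.00044) and Mbl2 (−0.93 ± 0.14, adjusted p = 0.0042) lower and the mitochondrial gene ND2 (1.10 ± 0.13, adjusted p = 0.00044) higher in PFOA5. Cyp2e1 was dim in PFOA5 and Mbl2 in both groups. Ehhadh (0.22, 95% interval −0.03 to 0.47) and Cyp4a14 (0.13, 95% interval −0.52 to 0.78) did not differ past the threshold. The 15 became 7, 5 and 9 without fetal PFOA1 replicates 2, 3 and 5, and 25, 9, 8 and 6 without fetal PFOA5 replicates 1, 3, 4 and 5. Other settings gave 54 (array weights), 23 (erythroid score as a covariate), 9 (negative control median as a covariate) and 9 (only these groups), with 6 higher and 8 lower after centring. Limma called 0 genes between the fetal GenX doses, with 619 at an unadjusted p under 0.05, fewer than by chance. Intervals were −0.24 to 0.31 for Ehhadh and −0.72 to 0.71 for Cyp4a14.

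Between the compounds at their higher doses, 159 genes differed in maternal liver, 84 higher and 75 lower with PFOA. Cyp2c55 (2.23 ± 0.41, adjusted p = 0.011) and Cyp2b10 (2.10 ± 0.40, adjusted p = 0.013) were higher under PFOA5 than under GenX10, as were the lipid droplet gene Cidec (1.47 ± 0.28), Abcc4 (1.19 ± 0.20) and the stress-response gene Trib3 (1.05 ± 0.15). CAR and PXR targets were higher in 5 of 22 (10 adjusted over the list alone, median log2 change 0.44, camera adjusted p = 8.5e-15, adjusted p = 0.059 with an estimated correlation). Smcp (−2.01 ± 0.15), the vasopressin receptor gene Avpr1a (−1.35 ± 0.15), the glycogen-targeting gene Ppp1r3c (−1.13 ± 0.17) and Gulo (−1.01 ± 0.17) were lower under PFOA5. Cyp2c55 and Trib3 were dim in GenX10, Avpr1a and Ppp1r3c in PFOA5, and Smcp in both. Cholesterol synthesis and uptake genes were lower in 6 of 19 (17 adjusted over the list alone, median log2 change −0.41, camera adjusted p = 8.4e-27). Ehhadh (0.06, 95% interval −0.36 to 0.48), Cyp4a14 (0.10, 95% interval −1.21 to 1.40) and Pdk4 (−0.04, 95% interval −0.73 to 0.65) did not differ past the threshold. Ehhadh and Cyp4a14 under exposure lay near the highest mean level of any gene, which leaves little range. The count was 102, 85, 82 and 97 without maternal PFOA5 replicates 2, 3, 4 and 5, and 93, 103 and 104 without GenX10 replicates 2, 3 and 4. It was 281 with all 50 arrays, 325 with array weights, 271 with the negative control median as a covariate and 92 with only these groups.

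At their lower doses the compounds differed in 191 genes in maternal liver, 35 higher and 156 lower with PFOA. Tff3, dim in GenX2, was higher under PFOA1 (1.37 ± 0.18, adjusted p = 0.00051), and the triglyceride synthesis gene Lpin2 (−0.70 ± 0.11, adjusted p = 0.0060) was lower. Pdk4 (−1.96 ± 0.34), Acot3 (−1.61 ± 0.19) and Pex11a (−1.12 ± 0.21) were lower, but none of these 3 passed with only these groups fitted. Mitochondrial oxidation genes were lower in 14 of 21 (21 adjusted over the list alone, median log2 change −0.53, camera adjusted p = 2.2e-36), peroxisomal ones in 10 of 27 (21 adjusted over the list alone, median log2 change −0.46, camera adjusted p = 7.1e-32) and PPAR-responsive lipid handling in 6 of 28 (14 and 1 the other way adjusted over the list alone, median log2 change −0.32, camera adjusted p = 1.3e-13). Without maternal PFOA1 replicate 1, at control level, the count was 124. It was 100 and 83 without PFOA1 replicates 2 and 4, 91, 83 and 86 without GenX2 replicates 1, 2 and 3, and 1193 without GenX2 replicate 4. It was 412 with all 50 arrays, 492 with array weights, 309 with the negative control median as a covariate and 4 with only these groups, and 19 higher and 235 lower after centring.

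In fetal liver the lower doses differed in 239 genes, 134 higher and 105 lower with PFOA. Cyp2e1 (2.81 ± 0.26, adjusted p = 3.5e-06), Pon1 (2.15 ± 0.25, adjusted p = 8.2e-05), the hydroxysteroid dehydrogenase gene Akr1c14 (1.34 ± 0.23), Tff3 (1.16 ± 0.22), Slc27a5 (1.07 ± 0.14) and Mbl2 (0.86 ± 0.14) were higher under PFOA1. Acss3, a mitochondrial acyl-CoA synthetase (−1.32 ± 0.16), the transcription factor gene Sox11 (−0.88 ± 0.13) and Acot2 (−0.88 ± 0.16) were lower. Cyp2e1, Pon1 and Tff3 were dim in GenX2, Acss3 in PFOA1, and Akr1c14, Slc27a5, Mbl2 and Sox11 in both. Ehhadh (−0.21, 95% interval −0.47 to 0.05) and Cyp4a14 (−0.13, 95% interval −0.81 to 0.54) did not differ past the threshold. The count was 1194, 135, 78, 153 and 121 without fetal PFOA1 replicates 1 to 5 in turn and 90 without GenX2 replicate 4. It was 433 with all 50 arrays, 916 with array weights, 124 with the erythroid score and 139 with the negative control median as a covariate, 368 among genes above the median level and 67 with only these groups. Median differences were −0.20 for erythroid markers (camera adjusted p = 3.9e-07, adjusted p = 0.60 with an estimated correlation) and −0.33 for cell cycle genes (camera adjusted p = 1.5e-10, adjusted p = 0.60 with an estimated correlation). Grouping the arrays of conflicting labels by source name gave 68 genes, leaving them out 131, and centring 99 higher and 319 lower.

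At the higher doses 345 genes differed in fetal liver, 300 higher and 45 lower with PFOA, and no named gene kept its call in every setting. Ehhadh (−0.03, 95% interval −0.30 to 0.24), Cyp4a14 (0.01, 95% interval −0.69 to 0.70) and Acaa1b (0.00, 95% interval −0.37 to 0.38) did not differ past the threshold. Median differences were −0.15 for erythroid markers (camera adjusted p = 2.0e-05, adjusted p = 0.76 with an estimated correlation) and −0.30 for cell cycle genes (camera adjusted p = 4.7e-10, adjusted p = 0.76 with an estimated correlation). The count was 139, 19, 23, 19 and 21 without fetal PFOA5 replicates 1, 2, 3, 4 and 6, and 17, 11 and 11 without GenX10 replicates 1, 2 and 4. Centring gave 40 higher and 24 lower, a repeated quantile normalization 17 and 19, and the erythroid score as a covariate 31 genes in all. Leaving out the arrays of conflicting labels gave 22, grouping them by source name 31, the negative control median as a covariate 14, moderation with a trend 124, all 50 arrays 183 and array weights 1018.

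Changed genes were shared between exposures in the 4 pairs compared per tissue, and none of those shared went opposite ways. In maternal liver PFOA5 and GenX10 shared 3146 genes in the same direction (424.1 for independent lists). In fetal liver they shared 818 (47.5 for independent lists), PFOA1 and GenX2 265 (11.1), PFOA1 and PFOA5 267 (6.4), and GenX2 and GenX10 1702 (95.3). In maternal liver GenX2 and GenX10 shared 966 (74.4), and the 10 genes of PFOA1 were all called the same way in PFOA5 (1.1) and in GenX2 (0.2). Both comparisons of a pair used the same controls. Simulated unchanged groups against these shared 0 limma calls on average. This decides little, as splits of real arrays called up to 3297 genes (fetal GenX10). With controls split between the comparisons, mean shared counts were 1166.7 for maternal PFOA5 and GenX10 and 355.4 for maternal GenX2 and GenX10. For maternal PFOA1 they were 1.9 with GenX2 and 2.4 with PFOA5. In fetal liver they were 355.4, 134.5, 135.5 and 586.9 in the fetal order above.

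Log2 changes over all genes, which are not independent replicates, correlated at r = 0.53 between maternal PFOA1 and PFOA5, the lowest of the 8 pairs compared, 0.89 between maternal PFOA5 and GenX10 and 0.93 between fetal GenX2 and GenX10, the highest. Shared controls alone gave 0.50, 0.50 and 0.47, and split controls 0.34, 0.78 and 0.74. The covariances exceeded the simulated ones by 0.0131, 0.0619 and 0.0427. In fetal liver 221 genes were higher and 29 lower in all 4 exposures. Across both tissues, maternal PFOA1 left aside, 144 genes were higher and 2 lower in every exposure. The higher ones included Ehhadh, Cyp4a14, Pdk4, Acot1, Acot2, Vnn1, Plin2 and Fabp1, and the 2 lower ones were Ces1c and Mbl2. Maternal and fetal liver, with separate controls, shared 5 genes with PFOA1 (0.1 for independent lists), 612 with PFOA5 (107), 339 with GenX2 (37.3) and 1128 with GenX10 (195.4) in the same direction. Opposite directions were called for 24, 7 and 22 genes with PFOA5, GenX2 and GenX10.

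Between unexposed tissues, 19116 genes differed, 32.2% of them higher in fetal liver. Afp, the fetal counterpart of albumin (6.27 ± 0.15), the granulocyte genes Stfa2l1 (6.99 ± 0.12) and S100a8 (5.90 ± 0.22) and Cd24a (6.21 ± 0.18) were higher in fetal liver. Sult3a2 (−7.97 ± 0.47), Cyp2c39 (−7.71 ± 0.11), the proteinase inhibitor gene Mug1 (−7.49 ± 0.14), Sult3a1 (−7.26 ± 0.70) and Mup3 (−7.07 ± 0.19) were higher in maternal liver. Each of these 9 was dim in the other tissue. Erythroid markers were higher in fetal liver in 21 of 23 (22 adjusted over the list alone, median log2 change 3.27, camera adjusted p = 8.6e-33), markers of fetal hepatocytes and progenitors in 11 of 11 (11 adjusted over the list alone, median log2 change 1.88, camera adjusted p = 8.1e-18) and cell cycle genes in 23 of 23 (23 adjusted over the list alone, median log2 change 2.34, camera adjusted p = 2.2e-28). CAR and PXR targets were lower in fetal liver in 19 of 22 (19 adjusted over the list alone, median log2 change −2.70, camera adjusted p = 1.0e-11) and growth hormone and sex-biased genes in 17 of 18 (17 adjusted over the list alone, median log2 change −2.47, camera adjusted p = 3.9e-11). Genes of the urea cycle were lower in 19 of 23 (19 adjusted over the list alone, median log2 change −1.10, camera adjusted p = 1.4e-09) and bile acid genes in 17 of 20 (17 adjusted over the list alone, median log2 change −1.76, camera adjusted p = 8.9e-08). The median over all genes was −0.131, so these differences are relative to a shifted scale, and centring gave 7109 higher and 9357 lower (6742 and 8663 after a repeated quantile normalization). Higher calls outnumbered lower ones with a 1.5-fold minimum (2584 and 1726) and with the negative control median as a covariate (4775 and 3703), and among genes above the median level they numbered 5017 and 5492.

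The effect of each exposure was then compared between tissues as an interaction, positive where the fetal change was the greater. With PFOA1, 55 genes differed, with Ces1g (2.86 ± 0.37), the lipase gene Abhd6 (2.10 ± 0.20), the muscle-type carnitine transferase gene Cpt1b (2.09 ± 0.29), Ehhadh (1.91 ± 0.25) and Acot3 (1.89 ± 0.27) higher and Fabp5 (−0.95 ± 0.19) and Hsd11b1 (−0.84 ± 0.15) lower. Ces1g, Abhd6, Cpt1b and Acot3 were dim in fetal controls, Hsd11b1 in both fetal groups, and Fabp5 and Cpt1b in both maternal groups. Without maternal PFOA1 replicate 1, at control level, 73 genes differed and maternal Ehhadh rose more (1.72). Mitochondrial oxidation genes were higher in 8 of 21 (13 adjusted over the list alone, median log2 change 0.50, camera adjusted p = 1.7e-35) and peroxisomal ones in 6 of 27 (11 adjusted over the list alone, median log2 change 0.44, camera adjusted p = 7.0e-28). With PFOA5, 1376 genes differed. Sult2a1 (4.81 ± 1.16), Sult2a2 (3.92 ± 0.95) and Cyp4f14 (3.58 ± 0.30), which fell in dams, were positive. Cyp4a12a (−4.89 ± 0.85), Fabp3 (−3.58 ± 0.35), Ly6d (−3.52 ± 0.42), Abcc3 (−3.40 ± 0.31), Cyp2c55 (−2.39 ± 0.43) and Cyp2b10 (−2.26 ± 0.42) were negative. Sult2a1, Sult2a2, Cyp4f14, Fabp3, Cyp2c55 and Cyp2b10 were dim in fetal controls and fetal PFOA5, as were Ly6d and Abcc3 on all but 1 array each, so these values restate the maternal change. Cyp4a12a was dim in maternal controls. Array weights gave 2891 genes for this comparison.

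With GenX2, 393 genes differed between the tissues. Cyp2e1 (−3.06 ± 0.30), Pon1 (−2.94 ± 0.28), Amy2b (−2.80 ± 0.59) and Abcc3 (−2.33 ± 0.32) were negative. Ces1g (2.95 ± 0.37), Aldh1a7 (2.63 ± 0.40) and the leptin receptor gene Lepr (2.20 ± 0.40) were positive. Abcc3 was dim in both fetal groups, Amy2b and Lepr in both maternal groups, Cyp2e1, Pon1 and Amy2b in fetal GenX2, and Ces1g, Aldh1a7 and Lepr in fetal controls. Cell cycle genes were positive in 5 of 23 (15 adjusted over the list alone, median log2 change 0.52, camera adjusted p = 1.8e-20, adjusted p = 0.16 with an estimated correlation). With only the 4 groups involved fitted the count was 260. With GenX10, 626 genes differed, 941 with array weights. Fabp3 (−3.99 ± 0.37), Cyp4a12a (−4.39 ± 0.90), Ly6d (−3.82 ± 0.44) and Cyp2e1 (−3.09 ± 0.31) were negative, and Mup21 (3.06 ± 0.39), Mup3 (2.82 ± 0.28), Ces1g (2.82 ± 0.38) and Serpina16 (2.41 ± 0.42) positive. Fabp3, Ly6d, Mup21, Mup3 and Serpina16 were dim in both fetal groups, so their values restate the maternal change, Cyp2e1 was dim in fetal GenX10, Ces1g in fetal controls and Cyp4a12a in maternal controls. Cholesterol synthesis and uptake genes were negative in 11 of 19 (15 adjusted over the list alone, median log2 change −0.72, camera adjusted p = 1.9e-22).

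**Figure D4:**
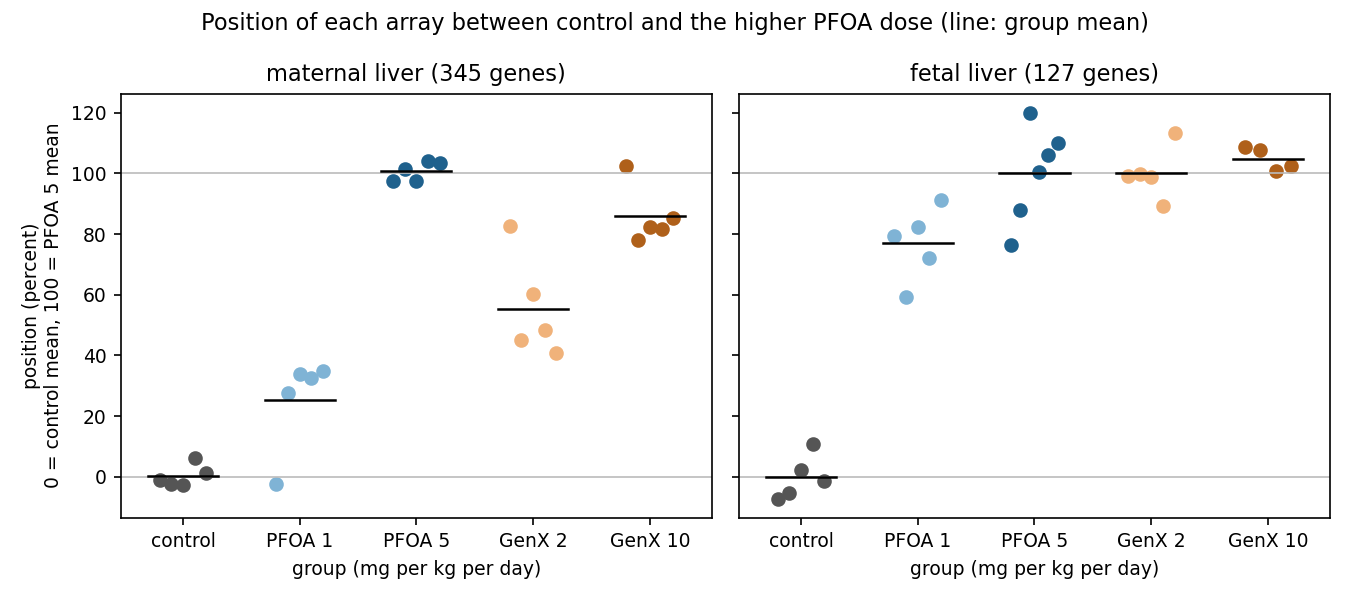
Position of each array on an axis from the mean of its tissue's controls (0%) to the mean of PFOA5 (100%), as the median over genes changed at least 2-fold in that comparison (345 maternal, 127 fetal genes), so that PFOA5 lies near 100% by construction; points are arrays and lines group means. Maternal PFOA1 replicate 1 lies at −2.5% while the other 4 arrays of its group lie at 27.5% to 34.9%, and the fetal PFOA1 arrays lie at 59.3% to 91.4%.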

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

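The tests of maternal PFOA1 replicate 1 at control level, of the fetal arrays with Y-linked signal and of the amylases were chosen after the results were seen, except those of the litter and of erythroid cells; the splits of the samples were planned.

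In maternal PFOA1, replicate 1 stood apart from its group for Ehhadh (10.54), Acaa1b (9.11), Cyp4a14 (8.55), Pdk4 (7.11), Cd36 (9.26), Angptl4 (7.91), Vnn1 (8.22) and Cyp2b10 (8.34). On the axis from control to PFOA5 it lay at −2.5%, inside the range of the controls (−2.6% to 6.1%), which a dam that did not take up the compound, or a wrong label, would give. The tables argue against a swap with a control array, since the highest control lay at 6.1% and the other 4 PFOA1 arrays at 27.5% to 34.9%. They also argue against poor array quality: its negative control median of 4.44 lay inside the range of the other maternal arrays (4.21 to 4.48), although it was far from the rest of its own group (4.4366), and its median correlation with its group was 0.9891 (others 0.9884 to 0.9951). If replicate numbers name litters, which the labels do not say, the position of fetal PFOA1 replicate 1 at 79.4% argues against a litter that no compound reached, and a low uptake by the dam alone and a wrong label remain open.

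Fetal control replicate 3 and fetal GenX2 replicate 2 combined low Xist with Y-linked transcripts. Xist lay at least 5.13 below the lowest of the other 23 fetal arrays, which argues against a mixture of male and female tissue with a sizeable female share. All 3 of 3 Y-linked genes were above every other fetal array in both: Eif2s3y (6.49 and 6.10, others at most 3.80), Kdm5d (5.66 and 5.50, others at most 4.06) and Uty (6.57 and 5.81, others at most 3.43). Afp lay within 0.12 of the mean of the other fetal arrays, which argues against a maternal liver under a fetal label. The values are consistent with RNA of male fetuses, and whether the fetus or the label is at fault stays open.

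The amylase genes were lower in exposed fetal liver, with Amy1, chosen after its values were seen, at −0.62, −1.06, −1.59 and −1.71 in PFOA1, PFOA5, GenX2 and GenX10 (limma adjusted p = 0.23, 0.0012, 1.0e-05 and 7.9e-06; control level 7.97 ± 0.47). Pancreas carried over in control livers cannot be told apart from a change in liver: 7 other pancreatic enzyme genes had a median change of −0.06 in GenX10 and −0.22 in GenX2, but their control means (5.41 to 7.32) lay below the 95th percentile of the negative controls (7.89), so they decide little, although Amy2a1 changed by −2.88 in GenX2 from a control mean of 6.30. The brightest of the 7, Ctrb1, changed by −0.11 in GenX10 and −1.02 in GenX2 (SD 0.95 in controls and 0.12 in GenX2, against 0.52 and 0.10 for Amy2b). Cross-hybridisation of the paralogs cannot be told apart from separate changes, because deviations within groups correlated between the amylases at as little as 0.17, neither together nor apart. A share of erythroid cells is argued against, since Amy1 changed by −1.70 in GenX10 with the erythroid score as a covariate. A lower amylase transcript level in exposed fetal hepatocytes may underlie the pattern and was not tested further.

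Single arrays far from their group were further found among 260 tests of quality measures and anchor genes, of which 29 stood out where chance gives about 13. Fetal PFOA1 replicate 1 had a median signal of 5.1923, and fetal GenX10 replicate 2 had 4393 genes above the negative controls. The median correlation with the rest of the group was low for fetal control replicate 5 (0.9915), fetal PFOA5 replicate 1 (0.9883) and fetal GenX2 replicate 4 (0.9919). Maternal GenX2 replicate 1 stood apart for Acaa1b (12.04) and Cyp2b10 (10.59), and maternal GenX10 replicate 2 for Fgf21 (9.88), Cyp3a11 (11.17) and Alb (13.32). Maternal control replicate 1 did so for the embryonic globin gene Hbb-y (8.11). Fetal PFOA1 replicate 2 stood apart for Cyp4a14 (12.10) and Pdk4 (10.35), fetal PFOA1 replicate 5 for Fgf21 (6.86) and Afp (12.86), and fetal PFOA5 replicate 3 for Cyp2b10 (5.65). So did fetal GenX10 replicate 1 for Pdk4 (11.86), fetal GenX10 replicate 2 for Sqle (9.24), fetal control replicate 3 for Cyp7a1 (8.78) and fetal control replicate 5 for Sqle (8.63).

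Effects that differed between tissues numbered 55 genes for PFOA1, 1376 for PFOA5, 393 for GenX2 and 626 for GenX10, by limma's interaction term. Among the anchor genes, the log2 change of Ehhadh was greater in fetal liver with every exposure (differences of 1.91, 0.98, 1.27 and 1.08 in that order). Its control level was 9.04 in fetal and 10.47 in maternal liver, and its maternal levels in PFOA5, GenX2 and GenX10 (13.01, 12.72 and 12.94) lay above the fetal ones (12.56, 12.56 and 12.59) and near the highest mean level of any gene (13.55), and so had little range left. With PFOA5 the fetal change was lower for Pdk4 (−2.35), Cd36 (−1.35), Cyp2b10 (−2.26), Cyp2c55 (−2.39) and Cyp8b1 (−1.49). Cyp2b10 and Cyp2c55 were not well above background in any fetal group (fetal control means of 5.01 and 3.82), so their differences restate the maternal change, and Cyp8b1 was above background on 1 of 6 fetal PFOA5, 2 of 5 GenX2 and 0 of 4 GenX10 arrays. With GenX2 it was higher for Angptl4 (0.91) and Vnn1 (1.50) and lower for Cyp8b1 (−1.44) and Ppara (−0.72). The Angptl4 call was lost without maternal control replicate 4 (adjusted p = 0.053) or fetal GenX2 replicate 5 (0.051). That of Vnn1 was lost, at adjusted p of 0.052 to 0.087, without maternal control replicates 2, 4 or 5, maternal GenX2 replicates 1 or 4, fetal control replicates 1, 2 or 5, or fetal GenX2 replicates 1 or 5. That of Ppara was lost, at adjusted p of 0.052 to 0.11, without maternal control replicates 1 or 3, maternal GenX2 replicates 1 or 2, fetal control replicates 2, 3 or 4, or fetal GenX2 replicates 2, 3 or 4. With GenX10 it was lower for Pdk4 (−2.12), Cyp8b1 (−1.86), Scd1 (−0.94) and Sqle (−0.74).

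The unnamed transcript clusters, 33206 in number and in no comparison above, held calls by limma against control. There were 1409 in maternal PFOA5, 116 in maternal GenX2 and 598 in maternal GenX10, and 37, 180, 373 and 559 in fetal PFOA1, PFOA5, GenX2 and GenX10.

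Each count of changed genes was ranked among 100 splits of the same arrays, the real one included. The share with as many was under 0.05, uncorrected, in 19 of 21 comparisons. In maternal liver, splits with as many genes numbered 4 for PFOA1 (10 genes, highest other split 60), 1 for PFOA5 (6109, 1560), 2 for GenX2 (1036, 1296), 1 for GenX10 (4232, 30), 1 for PFOA5 against PFOA1 (5748, 1961), 1 for GenX10 against GenX2 (73, 38), 1 for PFOA5 against GenX10 (159, 2) and 2 for PFOA1 against GenX2 (191, 1060). In fetal liver they numbered 2 for PFOA1 (293, 901), 1 for PFOA5 (1042, 874), 1 for GenX2 (2070, 10), 2 for GenX10 (2851, 3297), 1 for PFOA5 against PFOA1 (15, 7), 1 for PFOA5 against GenX10 (345, 8) and 1 for PFOA1 against GenX2 (239, 1). For fetal GenX10 against GenX2 (limma count 0) all 100 splits had as many. Fetal against maternal control had 1 (19116, 12522). The effects between tissues had 1 for PFOA1 (55, 42), 2 for PFOA5 (1376, 2804), 3 for GenX2 (393, 1732) and 5 for GenX10 (626, 5005), the last a share not under 0.05. Other splits called several times the real count in maternal PFOA1, maternal PFOA1 against GenX2, fetal PFOA1 and the GenX2 and GenX10 effects between tissues. This points to some structure of the samples, not identified, so the ranks do not exclude chance.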

How the results depend on the processing

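The fits without the fetal arrays with Y-linked signal and with the negative control median as a covariate were chosen after the data were seen; the other alternatives were planned. With the negative control covariate only counts were run, and camera was not run with all 50 arrays in 1 fit or with dam and fetus as a random block. Named gene calls numbered 1152 and list calls 340 over the comparisons, and no called gene changed direction in an alternative that was run on named genes. Gene calls were kept in 1117 cases with a trend and robust moderation, 1053 after quantile normalization again, 1075 after median centring, 1149 with averaged probes, 1140 with array weights, 910 with a 1.5-fold minimum and 976 with only the groups compared. Of the calls each alternative could test, 1056 of 1056 were kept among genes above the median level, 723 of 805 with all 50 arrays, 624 of 676 without the arrays of conflicting labels, 627 of 676 by source name, 615 of 676 without the arrays of Y-linked signal and 302 of 329 with the erythroid score. Of list calls, 86 were kept with an estimated correlation and 193 with fry. Leaving out 1 array kept 12255 of 13657 gene calls and 3565 of 3933 list calls. Signal near background limits what dim genes can show, and signal near the top limits Ehhadh and Cyp4a14. The causes of the movements below were not tested, except that fewer arrays or genes enter some fits and that a fold minimum can only lower a count.

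Directions turned in 3 list results that had been called: the neutrophil list in maternal GenX10 against GenX2 among genes above the median level (median −0.012), and in fetal PFOA5, with the erythroid score as a covariate, the cell cycle list (−0.007) and the erythroid list itself (0.001, by construction).

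Counts of genes that moved by over 1.5 times were as follows. With a 1.5-fold minimum they were 1084, 312 and 827 in maternal PFOA5, GenX2 and GenX10; 802 for PFOA5 against PFOA1, 40 for GenX10 against GenX2, 58 for PFOA5 against GenX10 and 62 for PFOA1 against GenX2 in maternal liver. In fetal liver they were 155, 326, 506 and 693 for the exposures, 8 for PFOA5 against PFOA1, 137 for PFOA5 against GenX10 and 78 for PFOA1 against GenX2. They were 4310 between control tissues, and 586, 254 and 373 for the effects of PFOA5, GenX2 and GenX10 between tissues. With array weights they were 38, 9637 and 2621 in maternal PFOA1, PFOA5 and GenX2, 325 and 492 in the maternal compound comparisons at the higher and lower doses, 54, 1018 and 916 in fetal PFOA5 against PFOA1, PFOA5 against GenX10 and PFOA1 against GenX2, and 2891 and 941 for the effects of PFOA5 and GenX10 between tissues. With all 50 arrays they were 58 in maternal PFOA1, 146 for maternal GenX10 against GenX2, 281 and 412 for the maternal and 183 and 433 for the fetal compound comparisons, higher doses first. With only the groups compared they were 0 in maternal PFOA1 (limma; 1719 at an unadjusted p under 0.05), 597 in maternal GenX2, 14, 92 and 4 for maternal GenX10 against GenX2, PFOA5 against GenX10 and PFOA1 against GenX2, 1159 and 1751 in fetal GenX2 and GenX10, 9 and 67 for fetal PFOA5 against PFOA1 and PFOA1 against GenX2, and 260 for the GenX2 effect between tissues. With the negative control median as a covariate they were 48 in maternal PFOA1, 271 and 309 for the maternal compound comparisons, 3155 in fetal GenX2, 9 for fetal PFOA5 against PFOA1, 14 and 139 for the fetal compound comparisons and 8478 between control tissues.

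Fetal PFOA5 against GenX10 gave 124 genes with trend and robust moderation, 36 after quantile normalization again, 64 after median centring, 31 with the erythroid score, 22 without the arrays of conflicting labels and 31 by source name. Fetal PFOA1 against GenX2 gave 368 genes among those above the median level, 418 after median centring, 124 with the erythroid score, 131 without the arrays of conflicting labels and 68 by source name. The erythroid score gave 23 for fetal PFOA5 against PFOA1, source names gave 1260 for fetal GenX2, the median level filter 10509 between control tissues, and quantile normalization again 16 for maternal PFOA1.

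Pairing by replicate number was neither clear nor excluded. Same-number deviations correlated above 0.1 in 10 of 50 maternal, 12 of 46 fetal and 5 of 24 dam and fetus pairs. With their own number, 9, 10 and 3 arrays correlated best. With the replicate block, fetal PFOA5 against GenX10 gave 10 genes and no other count moved by over 1.5 times. The block kept 745 of 805 gene and 253 of 264 list calls. A random block of dam and fetus by number kept 325 of 347 gene calls between tissues.

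Leaving out 1 array at a time gave 1 to 127 genes in maternal PFOA1, 702 to 2433 in maternal GenX2, 2364 to 4317 in maternal GenX10, 3637 to 6718 for maternal PFOA5 against PFOA1, 35 to 126 for maternal GenX10 against GenX2, 82 to 138 for maternal PFOA5 against GenX10 and 83 to 1193 for maternal PFOA1 against GenX2. In fetal liver the ranges were 1310 to 2016 in GenX2, 1547 to 3991 in GenX10, 5 to 25 for PFOA5 against PFOA1, 11 to 485 for PFOA5 against GenX10 and 78 to 1194 for PFOA1 against GenX2. The other counts stayed within 1.5 times.

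Shared genes with a 1.5-fold minimum numbered 588 for maternal PFOA5 and GenX10, 284 for maternal GenX2 and GenX10, 262, 143, 141 and 469 for fetal PFOA5 with GenX10, PFOA1 with GenX2, PFOA1 with PFOA5 and GenX2 with GenX10, and 189, 110 and 286 between tissues for PFOA5, GenX2 and GenX10. With split controls they were 1166.7, 1.9, 2.4 and 355.4 for maternal PFOA5 with GenX10, PFOA1 with GenX2, PFOA1 with PFOA5 and GenX2 with GenX10, and 355.4, 134.5, 135.5 and 586.9 for the fetal pairs in that order of compounds.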

Other observations

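Genes outside the groups described so far also moved in maternal liver. Of unfolded protein and integrated stress response genes, 11 of 18 were lower and 2 higher in maternal PFOA5 (11 and 3 adjusted over the list alone, median log2 change −0.34, camera adjusted p = 0.025, adjusted p = 0.51 with an estimated correlation), with the chaperone partner Sdf2l1 at −0.84 and Trib3, not well above background in controls, at 1.02. Nuclear receptor and coregulator genes were higher in maternal GenX2 in 5 of 19 (11 adjusted over the list alone, median log2 change 0.30, camera adjusted p = 1.5e-07). Ketogenesis was represented by 3 genes, of which 2 were higher in maternal PFOA5, GenX2 and GenX10 and in each fetal exposure.

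In fetal liver, lipoprotein and reverse cholesterol transport genes moved both ways, with 4 of 19 higher and 5 lower in GenX2 (4 and 5 adjusted over the list alone) and 3 higher and 5 lower in GenX10 (6 and 5 adjusted over the list alone). Mttp, which loads lipid onto lipoproteins, rose by 1.03 in PFOA5, 1.04 in GenX2 and 1.19 in GenX10. Macrophage and Kupffer cell markers had a negative fetal minus maternal effect in 3 of 16 (10 adjusted over the list alone, median log2 change −0.52, camera adjusted p = 6.1e-08, adjusted p = 0.24 with an estimated correlation) for PFOA5 and in 3 of 16 (12 adjusted over the list alone, median log2 change −0.58, camera adjusted p = 2.4e-10, adjusted p = 0.12 with an estimated correlation) for GenX10.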
